A study of Drosophila melanogaster with 24 samples.

How the data were processed

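RNA was measured in fat body of w1118 virgin females in 24 libraries, 6 in each of 4 groups (11 °C or 25 °C, with ethanol or S-methoprene), and the groups were taken from the labels. Per the labels' protocols, flies were moved into their condition soon after eclosion and kept there for 25 days, with 10 µL of ethanol or of S-methoprene in ethanol volatilised once every 2 days, and 25 flies went into a replicate. Poly-A RNA was selected on beads, fragmented and sequenced on an Illumina platform. Nothing in the labels ties a library to a batch or a date. Because flies were selected by ovary morphology, the groups differ in ovary state by construction.

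Per the submitters' processing notes, FastQC, Trim Galore, cutadapt, Bowtie2, SAMtools, Picard and DESeq2 were used with genome build dm6. Versions, parameters, the read counter, the strand setting and the gene annotation are not given in the sources used here. The series text speaks of chromatin accessibility, so whether each of these tools was run on the RNA libraries is not certain.

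The authors deposited 1 table of 13234 genes with 6 values each. Per the file headers, the first is a mean over libraries, a normalised read count in the signal unit, with no error of its own. Fold change and its standard error were deposited on the log2 scale, the test statistic is a score in the deposited table, and a p-value and an adjusted p-value follow, per the file headers. Checked on the values, the deposited statistic equals the fold change divided by its standard error, the deposited p-value is the two-sided normal one, and the adjusted values are Benjamini-Hochberg over 11399 genes. A p-value was empty for 40 genes and an adjusted p-value for a further 1795, all of which stay out of the calls. The means sum to 4719004, a normalised size of an average library, but the depth of single libraries, the spread between replicates and the count intervals are unknown. Precision was read from the deposited standard errors, whose median was 0.13 (log2) for genes at or above the median mean of 50.0. Values per library, and so tests of groups, leave-one-out fits, other splits of the samples and outlier checks, could not be computed. The p-values measure the spread between the libraries in the authors' fit.

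The table names no factor and no direction. To learn what model could have given it, the ceiling of the deposited standard errors (3.01, reached by 544 genes) was compared with that predicted for 7 kinds of model and up to 256 layouts of libraries each, with the default settings of DESeq2, the tool the authors name (fitted means of at least 0.5 and dispersion at most the larger of 10 and the number of libraries). Only an additive model of 2 factors with 23 libraries, in cells of 6, 6, 6 and 5, met the ceiling within a tolerance of 1e-09, and 100.0% of the steps between the 20 distinct fold changes of these genes fitted it. The steps were compared only for layouts that met the ceiling, so they do not set this model against the others. The closest other kind of model, 1 factor with 2 levels, missed the ceiling by 0.000498. This rests on default settings having been used. It leaves open which factor was compared, which side is positive and which library was left out, and none of these was read from gene values.

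The design written before the data were examined had tests for counts or values per library. As the table holds only the authors' comparison, the case written for it was used: the authors' adjusted p under 0.05, counted by direction. The named genes were fixed by rule beforehand: the 6 highest and 6 lowest fold changes among called genes at or above the median mean and with a gene name, and from each list the up to 4 members with the smallest adjusted p, or the 2 with the highest mean where none was called. The rule took 151 genes, of which a part is printed. Genes outside the rule are marked where they appear.

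There were 38 gene lists fixed beforehand, with markers of other cell types among them. Each was tested with cameraPR of limma 3.58.1 in R 4.3.3 on the signed statistic of all genes with a p-value, at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 37 lists with at least 2 such genes. It asks whether a list lies to one side of the other genes. A correlation between genes could not be estimated without values per library, so which calls would hold under an estimated correlation is not known, and a preset correlation of 0.05 was run instead. Each list median was also set against 10000 random lists drawn, without the list's own members, from genes with an adjusted p-value in 20 bins of mean expression, and again in 5 bins of transcript length within each. The first draws of these lists could take a list's own members. Members were left out after the first percentiles had been seen, which moved some percentiles slightly and altered none of the outcomes. A further 12 gene families were chosen after the values were seen and are reported apart. Transcript length is the longest annotated transcript of the Ensembl release 115 annotation, BDGP6.54, which shares the release 6 coordinates of dm6, and 13183 genes (99.6%) were matched by symbol or synonym. For a length adjustment chosen after seeing the data, the statistic was regressed on natural splines of log length and log mean with 5 degrees of freedom each in 13143 genes, which took up 10.3% of its variance.

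Alternatives to the threshold, to the mean expression filter, to the multiple testing correction and to the list test were run as listed beforehand, and those that need values per library were not: other normalisation, other tests on counts, the low count filter, the pseudocount, a fit of 2 groups only, leave-one-out fits, the replicate block and an estimated correlation. Data were simulated with the deposited standard errors of 11400 genes and 200 changed genes, all of the latter with a mean of at least 10. The calling step recovered 54.0% of genes changed by 0.5 on the log2 scale, 92.0% of those changed by 1 and 100.0% of those changed by 2 or 3, with 4.95% false calls. Errors were drawn independently from the same standard errors that the test used, so the rate of false calls follows from the set-up. It does not check the authors' fit. Far fewer genes were changed than the 49.0% called in the data, so the recovery rates apply to an unlike setting. For the list test, independent normal statistics were drawn apart from that simulation. A list shifted in them had a list-test p of 3.44e-11, and 2.2% of 500 unshifted lists fell under 0.05. With no correlation between the simulated genes, this rate does not carry over to lists of genes expressed together. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.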

Results

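The study profiled messenger RNA in fat body, the insect tissue that stores lipid and glycogen and makes yolk and immune proteins, dissected from virgin w1118 Drosophila melanogaster females. There were 4 groups of 6 libraries each. Flies were kept for 25 days at 11 °C or at 25 °C, and at each temperature they were given either ethanol alone or S-methoprene, an analogue of juvenile hormone. Each library came from 25 flies, and per the labels the dissected flies were kept only if the ovaries looked as their condition called for, regressed at 11 °C with ethanol and large in the other groups. The design asks which genes differ in adult diapause, the reproductive arrest entered in the cold, and which of these follow the hormone. The authors' deposited table holds 1 comparison of 13234 genes and no value per library, so the depth of each library is unknown. The table does not name the factor compared or the direction of its fold changes. Genes are therefore described as higher on the positive side or higher on the negative side of that comparison, and neither side was assigned to a temperature or to a treatment. The arithmetic of the deposited standard errors matches a fit of 23 of the 24 libraries with 1 term for each factor, 12 libraries on one side and 11 on the other, so that a fold change is the effect of 1 factor averaged over the other.

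The comparison was broad. Of 11399 genes with an adjusted p-value in the authors' deposited table, 5590 passed 0.05, which is 49.0%. Of these, 3078 were higher on the positive side and 2512 on the negative side. At least 4-fold changes were found in 484 genes on the positive side and 206 on the negative side. The median log2 fold change of called genes was 0.91 on the positive side and -0.65 on the negative side. These counts and medians cover genes of every mean. With a mean of at least 10, calls were about even, 2380 on the positive side and 2385 on the negative side. With a mean of at least 100 they were 1539 and 1532. The excess of positive calls thus lay among genes of low mean.

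The largest positive fold changes among well-expressed named genes in the authors' deposited table belonged to NimC4, a phagocytosis receptor of the Nimrod family, at a log2 fold change of 6.47 (SE 0.46, adjusted p = 3.81e-43), and hll at 4.89 (SE 0.38, adjusted p = 5.71e-35). In the same table salr, a zinc-finger transcription factor, stood at 4.21 (SE 0.28), the maltase Mal-A7 at 3.47 (SE 0.45), stl at 3.21 (SE 0.38) and the cold-inducible gene Fst at 3.17 (SE 0.31). On the negative side the authors' deposited table put the vitelline membrane gene Vm34Ca at -6.76 (SE 1.46, adjusted p = 2.03e-05), the lysozyme LysB at -6.29 (SE 0.41, adjusted p = 1.03e-49) and Fad2, also known as desatF, a desaturase of female cuticular hydrocarbons, at -6.26 (SE 0.75, adjusted p = 3.06e-15). The eggshell genes Vm26Aa at -4.79 (SE 1.27) and Vml at -4.75 (SE 1.40) and the serine protease Jon66Ci at -4.74 (SE 0.86) followed in that deposited table. LysB and Jon66Ci belong to families of similar copies, as do the trypsin, cecropin and Hsp70 genes, and how the authors counted reads shared between copies or between overlapping genes is not given in the sources used here. In the release 6 annotation NimC4 (FBgn0260011) lies on 2L from 14047582 to 14048863 and hll (FBgn0286723) on 2L from 14027001 to 14029368. Fad2 (FBgn0029172) lies on 3L from 11023535 to 11024846, Vm34Ca (FBgn0003983) on 2L from 13411141 to 13411631, and Fst (FBgn0037724) on 3R from 9644978 to 9646154. All are protein-coding.

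**Figure D1:**
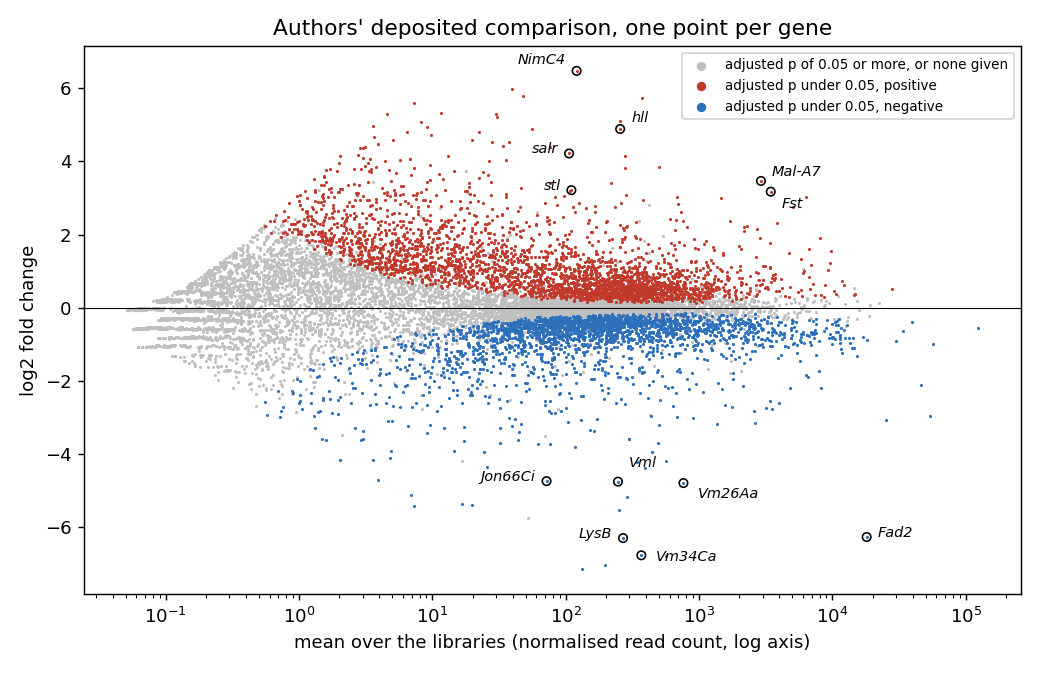
Log2 fold change (vertical axis) against mean normalised read count on a log axis (horizontal axis) for each gene of the deposited comparison, with called genes in red (positive, 3078 genes) and blue (negative, 2512 genes), and the 12 genes with the largest fold changes among well-expressed named genes circled. NimC4 reaches 6.47 and Vm34Ca -6.76.

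The yolk protein genes and part of the germline genes were called on the negative side. The 3 yolk protein genes, which fat body and follicle cells both express, were among the abundant transcripts, with log2 fold changes in the authors' deposited table of -3.05 for Yp1 (SE 0.36), -2.94 for Yp2 (SE 0.36) and -2.10 for Yp3 (SE 0.29). Of the 8 measured yolk and lipoprotein genes, 5 were called on the negative side and 2 on the positive side, and the same numbers held adjusted over the list alone. The positive ones were the lipocalin genes GLaz, at 1.16 (SE 0.15) in the deposited table, and NLaz. As a set this list did not pass the list test (adjusted p = 0.143). Of 21 germline genes, 10 were called on the negative side and 0 on the positive side, with 8 and 0 adjusted over the list alone, among them AGO3 at -2.06 (SE 0.43) and exu at -1.47 (SE 0.40) in the authors' deposited table. The germline list passed the list test (median -1.47, adjusted p = 0.0356). That call was lost with a preset correlation of 0.05 (adjusted p = 0.149), with genes of a mean of at least 10 only (adjusted p = 0.135) and with a mean of at least 100 (adjusted p = 0.399). Of 20 eggshell genes, 4 were called, all on the negative side, with 4 adjusted over the list alone, and 10 had no p-value in the deposited table (list test adjusted p = 0.0815). Of the cell-cycle genes, 20 of 33 were called on the negative side and 1 on the positive side (21 and 1 adjusted over the list alone; median -0.81, adjusted p = 0.00398). The deposited table gave -1.53 (SE 0.25) for the ribonucleotide reductase subunit RnrS, -1.84 (SE 0.41) for the origin recognition gene Orc1, -1.11 (SE 0.28) for dup, and 0.40 (SE 0.10) for Dp, the single positive one. The cell-cycle call was lost with a preset correlation of 0.05 (adjusted p = 0.0731), with genes of a mean of at least 10 only (adjusted p = 0.0507) and with a mean of at least 100 (adjusted p = 0.399).

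The ribosomal protein, mitochondrial ribosomal protein, ribosome biogenesis, proteasome and oxidative phosphorylation lists each passed the list test on the negative side. Of 83 ribosomal protein genes, 79 were called on the negative side and 1 on the positive side (80 and 2 adjusted over the list alone), with a median of -0.79 and an adjusted p of 1.92e-28 in the list test. RpS20 stood at -1.26 (SE 0.12), RpL35A at -1.01 (SE 0.10) and RpS29 at -1.50 (SE 0.16) in the authors' deposited table. The positive exception, RpS19b at 3.05 (SE 0.58) in that deposited table, is a paralogue with a mean of 4.79 and was picked out after the values were seen. Of 31 proteasome genes, 27 were called on the negative side and 0 on the positive side (29 and 0 adjusted over the list alone; median -0.46, adjusted p = 3.95e-11), with Prosbeta2 at -0.92 (SE 0.08) and Rpt2 at -0.66 (SE 0.08) in the authors' deposited table. Ribosome biogenesis genes gave 10 negative and 1 positive of 18 (10 and 1 adjusted over the list alone; median -0.37, adjusted p = 0.0178), led by Nop56 at -1.05 (SE 0.15) in the deposited table. Of 72 mitochondrial ribosomal protein genes, 31 were negative and 1 positive (31 and 0 adjusted over the list alone; median -0.29, adjusted p = 2.67e-05). Of 65 oxidative phosphorylation genes, 42 were negative and 3 positive (42 and 3 adjusted over the list alone; median -0.37, adjusted p = 2.67e-05), with ND-PDSW at -0.83 (SE 0.15) and Cyt-c1 at -0.60 (SE 0.11) in the authors' deposited table. The ribosome biogenesis call was lost with a preset correlation of 0.05 (adjusted p = 0.0894), with fold changes in place of the statistic (adjusted p = 0.148), and with a mean of at least 10 (adjusted p = 0.0912) or 100 (adjusted p = 0.140).

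Fold changes in the deposited comparison also went with transcript length, as a measured fact beside these groups. Over 6590 genes at or above the median mean expression, the Spearman correlation across genes of length and log2 fold change was 0.368, and genes are not independent replicates. With these genes split by length into 5 bins of equal size, the median log2 fold change was -0.32 in the bin with the shortest transcripts and 0.29 in the bin with the longest. In the shortest bin 166 genes were called on the positive side and 607 on the negative side, against 617 and 94 in the longest bin. After the statistic was adjusted for length and mean, ribosomal protein (adjusted p = 1.4e-09), proteasome (adjusted p = 3.66e-07), mitochondrial ribosomal protein (adjusted p = 0.0316) and oxidative phosphorylation (adjusted p = 0.0308) genes still passed the list test, while their medians moved to -0.34, -0.22, -0.02 and -0.09. Of the lists that did not pass before it, lipid metabolism (adjusted p = 0.00745), cytochrome P450 (adjusted p = 0.0138) and glutathione transferase (adjusted p = 0.0138) genes passed on the positive side after this adjustment.

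**Figure D2:**
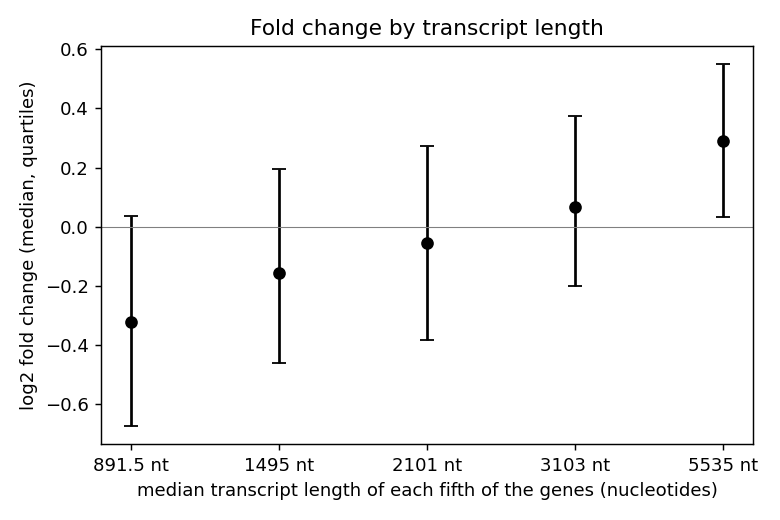
Log2 fold change (vertical axis; points are medians, bars span the quartiles over genes) in each of 5 bins of equal size of 6590 genes at or above the median mean expression, ordered by the length of the longest annotated transcript in nucleotides (horizontal axis). The medians run from -0.32 in the shortest bin to 0.29 in the longest.

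Sugar metabolism genes lay on the positive side. Of 23 genes of glycolysis, glycogen and trehalose metabolism, 15 were called on the positive side and 0 on the negative side, with the same numbers adjusted over the list alone (median 0.77, adjusted p = 1.58e-05). The authors' deposited table gave 3.02 (SE 0.31) for the glucosidase gene tobi, 1.76 (SE 0.22) for the glycogen branching enzyme AGBE, 1.03 (SE 0.14) for the trehalase Treh and 0.84 (SE 0.10) for the pyruvate kinase PyK. Of 7 genes with a known cold response, 5 were called on the positive side and 1 on the negative side (5 and 1 adjusted over the list alone; median 0.61, adjusted p = 0.00254). The cold list call was lost with fold changes in place of the statistic (adjusted p = 0.0532). Besides Fst these included smp-30 at 1.91 (SE 0.22) and the desaturase Desat1 at 0.51 (SE 0.08) in the authors' deposited table. The cold list shares Treh and Tps1 with the sugar metabolism list and Desat1 with the lipid metabolism list, so these list results are not independent. Of 27 lipid metabolism genes, 10 were positive and 2 negative (10 and 1 adjusted over the list alone; median 0.19, adjusted p = 0.0724). Lip3 stood at 3.72 (SE 0.42), the diacylglycerol acyltransferase mdy at 1.10 (SE 0.14) and the triglyceride lipase bmm at 0.86 (SE 0.20) in the deposited table. Insulin and FOXO genes gave 7 positive and 0 negative of 18, also adjusted over the list alone, with foxo at 0.58 (SE 0.09) and InR at 0.51 (SE 0.12) in the authors' deposited table, and the set did not pass (adjusted p = 0.0835). TOR and growth genes were split 4 to 4 of 16, also adjusted over the list alone (adjusted p = 0.968), with the TOR inhibitor Sesn at 1.24 (SE 0.09) and Myc at -0.66 (SE 0.19) in the deposited table.

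Juvenile hormone genes moved in both directions. Of 16, 5 were called on the positive side and 4 on the negative side, also adjusted over the list alone, and the set showed no common shift (median -0.03, adjusted p = 0.732). Both receptor genes were higher on the positive side, gce at 1.08 (SE 0.14) and Met at 0.64 (SE 0.11) in the authors' deposited table. The epoxide hydrolases went apart, Jheh1 at 1.04 (SE 0.09) and Jheh2 at -0.79 (SE 0.11) in that deposited table. The hormone response gene Kr-h1, named after its value was seen, was at -0.85 (SE 0.28) in the deposited table. Ecdysone genes gave 8 positive and 3 negative of 25, also adjusted over the list alone (adjusted p = 0.251). Among them were Eip93F at 1.02 (SE 0.10) and Eip71CD at -1.78 (SE 0.26) in the authors' deposited table. Of 9 circadian genes, 4 were positive and 2 negative, also adjusted over the list alone (adjusted p = 0.215). The clock genes per at 2.06 (SE 0.13) and tim at 1.62 (SE 0.20) opposed the photoreceptor gene cry at -1.24 (SE 0.12) in the deposited table.

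Among detoxification genes, 16 of 35 UDP-glycosyltransferase genes were called on the positive side and 3 on the negative side, also adjusted over the list alone (median 0.46, adjusted p = 0.0209), with Ugt302E1 at 1.94 (SE 0.27) and Ugt37D1 at 1.25 (SE 0.15) in the authors' deposited table. The call was lost with a preset correlation of 0.05 (adjusted p = 0.149) and with genes of a mean of at least 100 (adjusted p = 0.140). Cytochrome P450 genes gave 32 positive and 12 negative of 85, also adjusted over the list alone (adjusted p = 0.143). Members on opposite sides were Cyp6a2 at 2.20 (SE 0.17) and Cyp304a1 at -3.94 (SE 0.26) in the deposited table. Glutathione transferases gave 11 positive and 6 negative of 35, also adjusted over the list alone (adjusted p = 0.279). The oxidative stress genes were split, 8 positive and 5 negative of 19, also adjusted over the list alone (adjusted p = 0.817). Sesn, also in the TOR list, stood at 1.24 (SE 0.09), and Sod1 at -1.01 (SE 0.12) and Prx3 at -0.90 (SE 0.10) were negative in the authors' deposited table.

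The small heat shock gene Hsp23 stood at -3.58 (SE 0.32), Hsp68 at -1.89 (SE 0.33) and the constitutive chaperone Hsc70-4 at -0.90 (SE 0.12) in the authors' deposited table, while Hsp67Bc stood at 2.36 (SE 0.34). In all 5 of 16 heat shock genes were negative and 3 positive, also adjusted over the list alone (adjusted p = 0.133). Of 23 antimicrobial peptide genes, 2 were called on the negative side and 1 on the positive side, and 0 on either side adjusted over the list alone (median -0.79, adjusted p = 0.276), with DptB at -1.73 (SE 0.68) and CecC at -2.15 (SE 0.92) in the deposited table. Immune signalling genes gave 9 positive and 6 negative of 29, also adjusted over the list alone (adjusted p = 0.638). The members included the protease grass at 1.57 (SE 0.19) and the Imd inhibitor pirk at -1.60 (SE 0.26) in the authors' deposited table. The 5 Turandot genes gave 1 positive and 1 negative, 0 and 1 adjusted over the list alone (adjusted p = 0.817). Genes of the unfolded protein response gave 3 positive and 6 negative of 14 (adjusted p = 0.126), autophagy and lysosome genes 6 and 6 of 24 (adjusted p = 0.817), apoptosis and DNA damage genes 6 and 3 of 18 (adjusted p = 0.316), and chromatin genes 8 and 8 of 37 (adjusted p = 0.817). Adjusted over the list alone these 4 counts were 3 and 6, 6 and 6, 7 and 3, and 8 and 7. The histone demethylase Kdm2 at 1.07 (SE 0.11) and Atg13 at 0.81 (SE 0.11) were on the positive side in the authors' deposited table, and Atg14 at -0.77 (SE 0.09) on the negative side.

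**Figure D3:**
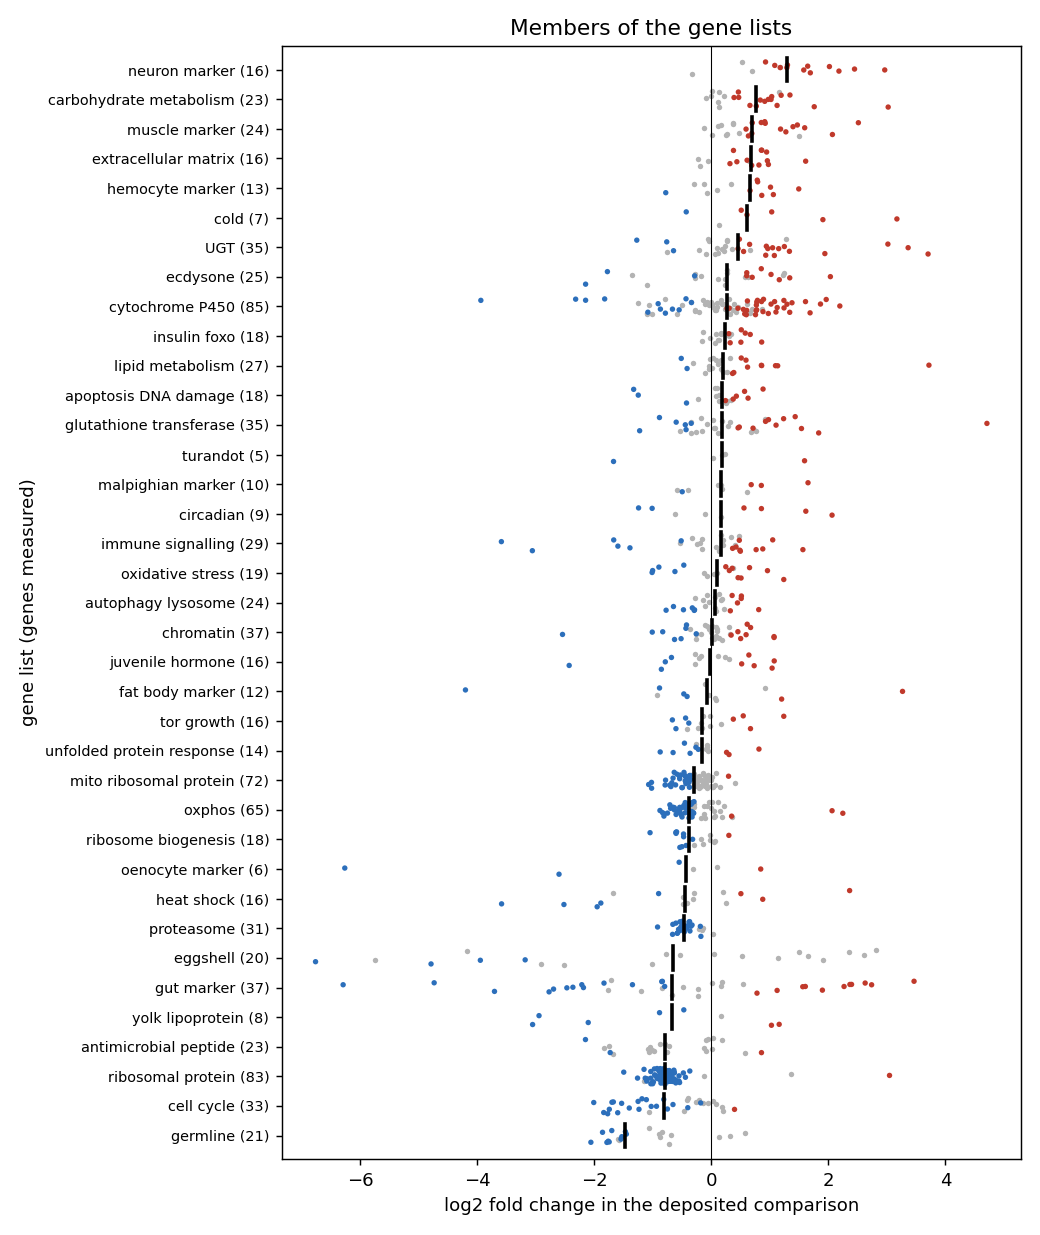
Log2 fold change in the deposited comparison (horizontal axis) of each member of the gene lists fixed beforehand with at least 5 measured genes (vertical axis, number measured in brackets), red where called on the positive side, blue where called on the negative side and grey otherwise, with a black bar at the list median. Medians of the lists shown run from -1.47 for germline genes to 1.30 for neuron markers, and that of the ribosomal protein genes is -0.79.

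Extracellular matrix genes and markers of muscle and nerve lay on the positive side. Of 16 matrix genes, 12 were called on the positive side and 0 on the negative side (13 and 0 adjusted over the list alone; median 0.67, adjusted p = 0.00114). The matrix call was lost with fold changes in place of the statistic (adjusted p = 0.145). The authors' deposited table gave the lysyl hydroxylase Plod at 1.61 (SE 0.15) and the collagen IV chains Col4a1 at 0.96 (SE 0.13) and vkg at 0.81 (SE 0.14). Muscle markers gave 14 positive and 0 negative of 24, also adjusted over the list alone (median 0.70, adjusted p = 0.00137). Among these were the myosin light chain Mlc2 at 1.60 (SE 0.18) and paramyosin Prm at 1.40 (SE 0.25) in the deposited table. Neuron markers gave 12 positive and 0 negative of 16 (13 and 0 adjusted over the list alone; median 1.30, adjusted p = 9.87e-05), with cpx at 1.58 (SE 0.14) and elav at 1.69 (SE 0.16) in the authors' deposited table. Neuron markers are long genes, and after the adjustment for length and mean their median was 0.60 and their adjusted p 0.220.

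Markers of the remaining cell types did not pass the list test as sets. Hemocyte markers gave 7 positive and 1 negative of 13, also adjusted over the list alone (median 0.66, adjusted p = 0.0762), with eater at 1.01 (SE 0.17) and PPO2 at 1.49 (SE 0.27) in the authors' deposited table. Oenocyte markers gave 1 positive and 3 negative of 6, also adjusted over the list alone (median -0.43, adjusted p = 0.0516), with the elongase eloF at -2.60 (SE 0.25) and the highest-mean gene of the table, Cyp4g1, at -0.55 (SE 0.15) in the deposited table. Gut markers were split 11 to 14 of 37, also adjusted over the list alone (median -0.67, adjusted p = 0.251), with deltaTry at -2.77 (SE 0.22) and Mal-A6 at 2.74 (SE 0.25) in the authors' deposited table. Malpighian tubule markers gave 3 positive and 1 negative of 10, also adjusted over the list alone (adjusted p = 0.251). Fat body markers gave 2 positive and 4 negative of 12, also adjusted over the list alone (median -0.07, adjusted p = 0.464). Negative members were the storage protein Lsp1beta at -4.20 (SE 0.68) and apolpp at -0.88 (SE 0.19) in the deposited table. Of 2 spermatheca markers, Send1 and Send2, 0 were called and 1 had a p-value, so the list was not tested.

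The design implies further comparisons: 11 °C against 25 °C under ethanol, S-methoprene against ethanol at each temperature, 11 °C against 25 °C under S-methoprene, the interaction of both factors, and the genes moved by diapause and returned by the hormone. None could be tested from a table of 1 unnamed comparison, and no result above stands for any of them.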

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

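Of the 20 eggshell genes measured, 10 are among the 40 genes left without a p-value in the authors' deposited table, where 0.0605 would be expected from the share of such genes (Fisher's exact test, two-sided, p = 3.39e-21), and the overlap was looked for only after the table was seen. Fisher's test takes genes as independent, which genes expressed together are not, so its p-value overstates the evidence. All 40 genes had a mean, a fold change and a standard error, and their values stand outside the calls. The means of these 10 genes ran from 5.05 to 424. Of these, 8 had a positive fold change in the authors' deposited table, but with standard errors such as 2.34 for Cp38 at 2.81 and 2.92 for Cp16 at 0.05. Larger beside their errors were yellow-g2 at 2.60 (SE 1.10) and Cp18 at -2.52 (SE 1.04), on opposite sides. No direction is read from these genes. Of the germline genes, 0 were without a p-value. No explanation was tested, as values per library were not analysed here.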

How the results depend on the processing

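The length adjustment, the filter at a mean of 100 for lists and the removal of 5 marker lists were chosen after seeing the data, and all other alternatives were planned. Calls on the positive and negative side were 1413 and 676 when an absolute log2 fold change of at least 1 was also required, 1539 and 1532 among genes with a mean of at least 100, and 1135 and 989 with Bonferroni correction. These settings are stricter or test fewer genes. Under the other thresholds, corrections and list removals both counts stayed within 1.5 times. Of the lists, 6 passed on the positive side and 7 on the negative side. The negative lists numbered 4 with a preset correlation of 0.05, 4 with a mean of at least 10, 4 with a mean of at least 100, and 12 with fold changes in place of the statistic, and the cause was not tested. Lists that passed only with fold changes, all on the negative side, were yolk and lipoprotein, antimicrobial peptide, heat shock, gut and oenocyte. The eggshell list passed with fold changes or ranks, and insulin and FOXO with ranks alone. Of the 13 lists called, 6 passed under every alternative of the list test: carbohydrate metabolism, ribosomal protein, mitochondrial ribosomal protein, proteasome, oxidative phosphorylation and muscle. Random lists matched on mean and length are not among these alternatives. Against them, the medians of the mitochondrial ribosomal protein, proteasome and oxidative phosphorylation lists lay within the central 95%. Of the 24 tested lists that were not called, 12 shifted to the other side under some alternative, never with an adjusted p under 0.254. Median, mean and test differed in sign for the juvenile hormone, immune signalling, Turandot, TOR, autophagy and chromatin lists. Requiring an absolute log2 fold change of at least 1 ended the call of 61 of 150 named genes with a p-value. Bonferroni correction ended that of 29, an adjusted p under 0.01 that of 8, and Benjamini-Hochberg over all genes with a p-value that of 2. No paired analysis was possible because the table holds no values per library. For the same reason other normalisation, other tests on counts, another pseudocount, a fit of 2 groups only, leaving out libraries, an estimated correlation and counts under other splits of the samples were not run. What depth limits was not measured, as the depth of the libraries is unknown.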

Other observations

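The gene families and tests of this part were chosen after the fold changes were seen, and the patterns tested already name a side. For standard errors and length in the cell-cycle list, the predictions were written before the comparisons were run. So were those for standard errors in the 3 protein and respiration lists together, and for length in the neuron and muscle lists. The other predictions were written afterwards.

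All 10 maltase genes, which split sugars, were called on the positive side (median 2.32, adjusted p = 1.36e-08 over 12 families). The authors' deposited table gave 2.74 (SE 0.25) for Mal-A6, 2.63 (SE 0.25) for Mal-A2, 1.90 (SE 0.24) for Mal-A1 and 0.53 (SE 0.12) for Mal-B2. The 8 Mal-A genes lie within 24.3 kb on 2R. Of the gut markers, 7 are maltases, and the other 30 had a median of -0.84. The Jonah serine proteases, 15 of 16 of them also gut markers, went the other way, 8 negative and 1 positive (median -1.46, adjusted p = 0.00148, lost after the adjustment for length and mean at 0.134), with Jon65Aiv at -2.18 (SE 0.25) and Jon25Bii at -3.70 (SE 0.48) in the deposited table. Median standard errors were above those of lists matched on mean, 2.16 times for maltases, 4.35 for Jonah genes and 2.76 for gut markers, and no cause was tested.

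Translation genes outside the ribosome went with it. Of 47 initiation and elongation factor genes, 29 were negative and 0 positive (median -0.57, adjusted p = 1.94e-13), led in the authors' deposited table by eIF3h at -1.37 (SE 0.09) and eEF1gamma at -1.31 (SE 0.10). Aminoacyl-tRNA synthetases gave 20 negative and 2 positive of 31 (median -0.41, adjusted p = 8.25e-08), the positive ones being the mitochondrial ArgRS-m and SerRS-m. Of 8 subunits of the cytosolic chaperonin, 7 were negative and 0 positive (adjusted p = 0.00593), and the call was lost with fold changes in place of the statistic (adjusted p = 0.172). Adjusted over the list alone, negative and positive counts were 8 and 1 for Jonah genes, 29 and 0 for the factors, 21 and 2 for the synthetases and 7 and 0 for the chaperonin, and 10 maltases were positive. Not passing were cuticle proteins with 18 positive and 2 negative of 77 (adjusted p = 0.102), odorant-binding proteins with 3 and 5 of 31 (adjusted p = 0.365), chemoreceptors with 13 and 2 of 93 (adjusted p = 0.38), sugar transporters with 3 and 1 of 7 (adjusted p = 0.134), Nimrod receptors with 3 and 3 of 8 (adjusted p = 0.269), pickpocket channels with 4 and 1 of 24 (adjusted p = 0.365) and proton pump subunits with 6 and 2 of 28 (adjusted p = 0.38). Adjusted over the list alone these 7 counts were 15 and 1, 3 and 5, 10 and 2, 3 and 1, 4 and 3, 4 and 1, and 4 and 2. Cuticle proteins passed with fold changes in place of the statistic (adjusted p = 2.3e-05) and after the length adjustment (adjusted p = 0.0382), and odorant-binding proteins with a mean of at least 100 (adjusted p = 0.0296). The odorant-binding mean was above 0 while its median and test were below. Among sugar transporters the trehalose transporter Tret1-2 stood at 2.48 (SE 0.19) in the deposited table.

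Neighbouring genes shared a side more often than under permutation. Of 2063 adjacent called pairs among genes at or above the median mean, 55.3% were on the same side, against at most 54.2% in 10000 permutations (permutation p = 0.0001, the smallest they can give). The genes with the highest positive fold changes by the naming rule, hll and NimC4, lie 18.2 kb apart on 2L. On chromosome 4, 25 of the genes at or above the median mean were called on the positive side and 9 on the negative side, a positive share of 73.5%. The share ran from 46.9% on 3L to 48.8% on 2L over the other arms. Transcript length was not taken into account, and no test was made.

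The cell-cycle and germline lists were on the negative side together, with 0 genes in common, and RNA from ovary cells in some libraries is a candidate source. The median standard error of the cell-cycle list was 1.94 times that of random lists matched on mean expression. The ratio was 3.26 for the germline and 6.59 for the eggshell list, as libraries that differ in such RNA could give. The eggshell ratio covers only 10 of 20 genes, those with an adjusted p-value. Of the 10 left out, 8 had a positive fold change, from which no direction is read. An effect limited to 1 of the 4 groups could raise these ratios as well in a model with no interaction, and the antimicrobial peptide list, whose genes fat body itself expresses, had a ratio of 4.92. Of the 5 germline genes with the highest means, osk (356), exu (131) and orb (117) were called negative in the authors' deposited table, yl (455) had a fold change of similar size, -1.59 (SE 0.73, adjusted p = 0.0588), and tud (1098) stood apart at 0.13 (SE 0.18, adjusted p = 0.562). Transcript length does not account for the cell-cycle shift, as the list median lay at percentile 0 of random lists matched on mean and length. Dissection was the only step that removed ovary, how many of these genes fat body expresses was not known, and a change within fat body stays open and was not tested.

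The ribosomal protein, proteasome and oxidative phosphorylation lists were on the negative side. For RNA from ovary cells carried over unevenly, in some libraries, the largest of the 3 ratios of standard errors was 1.04. Fat body expresses these genes too, so uneven carry-over could raise the ratio too little to be seen. The ratio does not speak to ovary RNA carried over evenly on one side, and both kinds of carry-over stay open. Against length as the whole cause for ribosomal protein genes, their median lay at percentile 0 of lists matched on mean and length. For the proteasome (percentile 3.47) and oxidative phosphorylation (percentile 10.6) lists the medians lay within the central 95% while the adjusted list test still passed, so length and a change of these groups cannot be told apart, and the mitochondrial ribosomal protein list, not among the 3, lay further inside at percentile 30.8. A response of fat body to temperature or hormone may underlie the ribosomal protein shift, a hypothesis that the unnamed sides leave untested.

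The neuron and muscle marker lists were on the positive side, and muscle tissue in some libraries is a candidate source for the muscle list, whose median standard error was 1.6 times that of matched lists. This does not single out muscle, since an effect limited to 1 group could raise it and the immune signalling list had a ratio of 1.81. The neuron list had a ratio of 1.04, but at its median mean of 10.8 the noise of low counts could hide uneven carry-over of nerve. Among lists matched on mean and length, the lower of the percentiles of the neuron and muscle lists was 99.4. Both medians thus lay outside the central 95%. The muscle list also passed the list test after the length adjustment (adjusted p = 0.00242), so length alone did not place it. The neuron list lost its call after that adjustment, when its median fell from 1.30 to 0.60. For the neuron list the 2 checks disagreed, so length as the whole cause stays open. A lower share of fat body on the positive side would raise every other cell type, and 4 of 7 such lists had positive medians (hemocyte 0.66), but 2 of 7, germline and gut, had negative medians below the central 95% of lists matched on mean. That speaks against it as the whole cause, weakly, since ovary state differs by design, the gut list was split 11 to 14 without passing (adjusted p = 0.251), and its test turned positive after the length adjustment (adjusted p = 0.254). Carry-over of nerve or muscle, even on one side or in some libraries only, and expression in fat body itself, stay open.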
